A study of Macaca mulatta with 20 samples.

How the data were processed

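Total RNA was extracted from colonic epithelium with a column kit that keeps small RNA and includes DNase digestion, then reverse transcribed, preamplified and run on human TaqMan miRNA panels, per the labels' protocols. These name OpenArray panels and, for loading, TLDA plates on a real-time PCR instrument, so the exact format was left open. The threshold cycles (Ct) were used as deposited by the authors, with 762 wells in 20 samples and a value of 40 where an assay did not amplify. Ct falls by 1 for each doubling of template at full efficiency, which was not measured here. Of the 762 wells, 381 on each panel, 8 were controls: RNU44, RNU48 and U6 on both panels, and a plant miRNA that read 40 in every sample. The second table, the authors' comparison of chronic SIV with what its header calls preinfection samples, holds a fold (a ratio), a p-value and an adjusted p-value per assay, per the file headers. The normalization and test behind this deposited table are not given in the sources used here, and neither is the rule for calling a Ct. Assays were designed for human, mouse and fruit fly sequences, so a macaque sequence difference can change a Ct, and assays for near-identical family members can detect one another.

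From the Ct values, each sample's mean Ct over the 227 miRNA assays detected in all 20 samples was taken as its reference, and relative levels were this reference minus the assay's Ct, on a log2 scale. The 350 miRNA assays detected in at least 15 of 20 samples were tested, and samples without amplification were left missing. Of the 350, 294 matched a miRNA gene by name in the annotation of the macaque assembly T2T-MMU8v2.0, which was used only for names and neighbouring genes. All columns of samples were used. Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05, and intervals are 95%. The comparisons were chronic SIV against uninfected in all samples, after against before infection in the 4 serially sampled animals with animal as a block, chronic SIV against uninfected in animals sampled once, the interaction of infection with serial sampling, and the 2 kinds of uninfected and of infected samples against each other. The fits over all samples treat the 20 samples as independent although 4 animals gave 2 samples each. Serial samples were paired by the animal in the sample titles. As a check, deviations from the group means in samples before and after infection correlated at 0.19 in HD08, -0.11 in HH07, -0.04 in HF54 and 0.03 in HR42. Between different animals they correlated at -0.13 to 0.12. Only HD08 lay above that range, so the check did not bear out the pairing. Identical Cts were looked for only in the most correlated pairs of samples, where none were found. The closest pair had a correlation of 0.973.

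Detection was compared with two-sided Fisher's exact tests. Lists of miRNAs fixed before the data were examined were tested with camera at a preset correlation of 0.01, with missing values set to the assay's lowest level, and again with an estimated correlation, over the 12 lists with at least 3 tested members. The rotation test fry called none of the 12. List membership overlapped: 5 of 12 leukocyte, 8 of 11 inflammation and 8 of 10 tight junction members were also in another list, and none of the smooth muscle or DLK1-DIO3 members was. Sample measures were compared by exact permutation of group labels. The miRNAs named were fixed by rule: up to 12 per direction with the largest change among those past the threshold, 2 miRNAs recalled from the study's publication, up to 4 members of each list with the smallest p, the 5 smallest p per direction in each further comparison, of which some are given here, and the 5 smallest p for detection. miR-223, and in the closing part miR-145, miR-125b, miR-27a, miR-27b, miR-23a and miR-23b, were named after their values were seen.

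The limma step was tested on simulated Ct values built from the spread and missing values of the 350 assays. Over all 20 samples it found 25.3%, 61.5% and 83.8% of changes of 1, 2 and 3 log2 units, with 3.22% false calls on average. Among animals sampled once it found 6.75%, 36.1% and 66.2%, with 3.02% false calls, and in the serial animals 0.251%, 0.251% and 3.01%, with 13.2% false calls. A list lowered by 1 log2 unit was called in 20 of 20 simulations, with 6 calls of other lists in total. The simulated assays varied independently of each other. In the data the estimated correlation was 0.25 in the leukocyte list and 0.451 in the smooth muscle list, so these simulations do not test camera under such correlation.

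Alternatives were endogenous controls, the sample median, quantile normalization or no normalization, a detection limit of Ct 37, filters of 10 or 20 samples, non-detects set to 40, eBayes with trend and robust settings, animal as a random or fixed block, a rank-sum test, and leaving out each sample or serial animal from the fit. Those chosen after seeing the data were the U6 gap between panels as a term, the 14 samples without and the 6 with a gap over 0.5 cycles, a reference per panel, the 3 serial pairs without a gap, the comparison of the deposited fold changes with each kind of uninfected sample, and Cts below 12 treated as not measured. The number of samples and the Ct scatter limit the precision, and p-values cover the spread between these samples.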

Results

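MicroRNA (miRNA) levels were measured by reverse transcription and quantitative PCR in epithelium isolated from the colon of rhesus macaques. The series held 12 samples from animals with chronic simian immunodeficiency virus (SIV) infection and 8 uninfected samples, from 16 animals in all. Animals HD08, HH07, HF54 and HR42 gave a sample before infection and a second one afterwards, labelled 90D for HD08 and 180D for the other 3, read here as days. The remaining 12 animals, 8 infected and 4 uninfected, were sampled once. The labels describe 3 uninfected animals given only THC and 1 given only vehicle, without saying which samples these were. The number matches the 4 uninfected animals sampled once, since the other uninfected samples came from animals that were later infected. The uninfected animals sampled once may thus mostly have been given THC. THC could not be separated from the comparisons below. Each sample was run on panels A and B, with 754 miRNA assays between them, and each assay gave a threshold cycle (Ct), where a lower Ct means more template and 40 stood for no amplification. Between 341 and 429 miRNA assays amplified per sample, and 167 amplified in none. The assays detected in every sample had a mean Ct of 21.2 ± 0.542 (SD, n = 8) in uninfected and 21.97 ± 0.528 (SD, n = 12) in infected samples, a difference of 0.77 cycles (two-sided exact permutation p = 0.00631, Benjamini-Hochberg adjusted p = 0.0442 over 7 sample measures). All levels below are relative to this mean.

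The small nuclear RNA U6 was measured on both panels and served to compare the panels within a sample. In 6 samples its Ct was 0.60 to 1.38 cycles later on panel B than on panel A, and in the other 14 the gap was 0.01 to 0.19 cycles. The 6 samples with the gap were 4 of the 8 uninfected samples (animals HR42 before infection, HT73, IH95 and IT05) and 2 of the 12 infected samples (FE24 and FT11). The gap went with the first principal component of the miRNA levels, which carried 35.9% of the variance, and 94 of 350 assays differed between samples with and without it at an adjusted p under 0.05 in limma with infection in the model. The gap did not follow the panel means of the reference miRNA assays. FT11, with a U6 gap of 0.88 cycles, had mean Cts of 21.76 on panel A and 22.2 on panel B. HF54 after infection, with a U6 gap of 0.03, had 21.08 and 25.66. The gap is therefore given beside each comparison as a possible technical batch, chosen after seeing the data. Samples without it can still differ between panels.

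**Figure D1:**
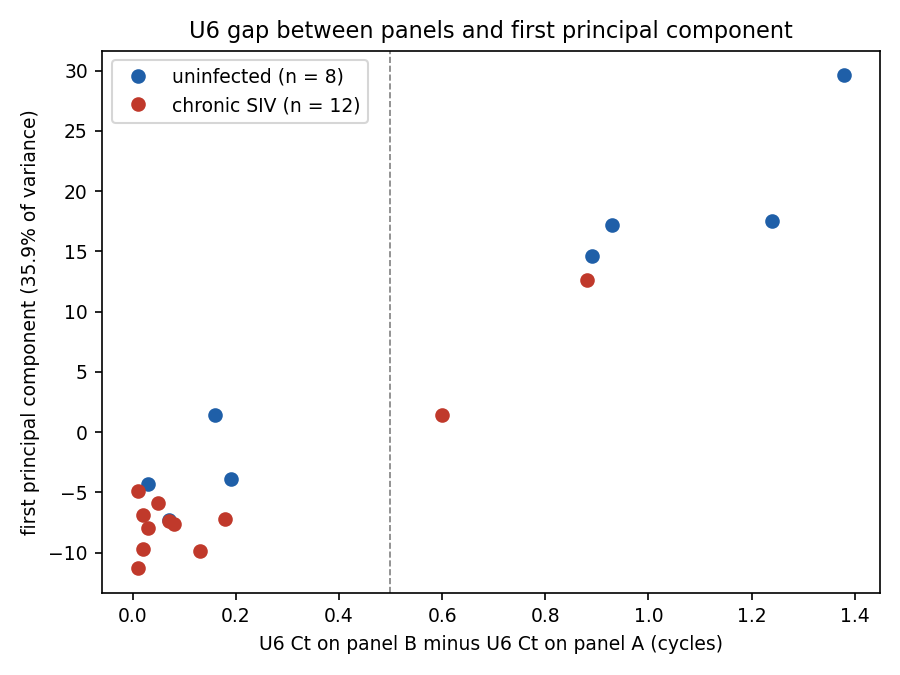
U6 Ct on panel B minus panel A (cycles, x axis) against the first principal component of the miRNA levels (y axis), with 1 point per sample and colour showing the group. The 6 samples to the right of the dashed line at 0.5 cycles include 4 of the 8 uninfected and 2 of the 12 infected samples.

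The series was designed to compare colonic epithelium of chronically infected and uninfected macaques. miR-130a rose 3.36-fold in chronic SIV infection (log2 change 1.75 ± 0.41 SE, 95% confidence interval 0.90 to 2.59, adjusted p = 0.0274), and all 12 infected samples lay above the uninfected median. miR-452, whose gene neighbours that of miR-224 in the macaque assembly T2T-MMU8v2.0, rose 5.29-fold (2.40 ± 0.54, adjusted p = 0.0274, 12 of 12 samples). Both measured arms of the miR-28 precursor fell, miR-28 by 1.32 ± 0.33 and miR-28-3p by 2.03 ± 0.50 on the log2 scale (both adjusted p = 0.0325, each lower than the uninfected median in 12 of 12 infected samples, as counted for the miRNAs that follow). The related miR-10a and miR-10b, encoded within HOX gene clusters, fell by 1.22 ± 0.33 (adjusted p = 0.0472, 12 of 12 samples) and 1.75 ± 0.50 (adjusted p = 0.0496, 11 of 12 samples). miR-194, abundant in intestinal epithelium, had a mean Ct of 14.4 ± 0.942 (SD, n = 8) in uninfected samples and fell by 1.22 ± 0.34 (adjusted p = 0.0496, lower in all 11 infected samples that amplified it), and miR-181a, a regulator of lymphocyte development, fell by 1.11 ± 0.31 (adjusted p = 0.0496, 11 of 12 samples). Unlike for miR-28, the other arm of these precursors did not pass. It had log2 changes of -0.28 for miR-10a and -0.46 for miR-181a, but 0.15 for miR-10b and 1.06 for miR-194.

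In all, 16 of 350 tested assays changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 6 of them higher and 10 lower in infected samples, and 103 had an unadjusted p under 0.05. The other 4 that rose were miR-99b (log2 change 4.79 ± 1.11 SE), the mouse-named assay for miR-137 (2.65 ± 0.64), miR-1255B (1.71 ± 0.48) and miR-200a# (1.54 ± 0.42), a passenger strand of the epithelial miR-200 family. The other 4 that fell were miR-338-5P, miR-520b, which belongs to a primate-specific cluster known from placenta (-4.39 ± 0.92), miR-532-3p (-1.10 ± 0.29) and miR-30b (-0.82 ± 0.24). The values of 2 of these assays were split within the uninfected group. miR-338-5P had Cts of 6.03 to 8.02 in 4 uninfected samples, 24.8 in 1 and no amplification in 3, against 19.6 to 29.9 in the 10 infected samples that amplified it. Those 4 Cts were earlier than the mean U6 Ct of uninfected samples, 8.765 on panel A and 9.376 on panel B. With Cts below 12 treated as not measured, this assay was no longer tested. Such early Cts were found for a mean of 15 ± 6.302 miRNA assays (SD, n = 8) per uninfected sample. In infected samples the mean was 7.083 ± 8.415 (SD, n = 12; two-sided exact permutation p = 0.0402, adjusted p = 0.0938). miR-99b had Cts of 20.3 and 20.8 in 2 uninfected samples, close to the infected mean of 21.9 ± 0.652 (SD, n = 12), 25.9 to 30.0 in 4 and no amplification in 2. The other arm of the precursor had a log2 change of -0.37 for miR-99b and 1 for miR-338-5P. It was 0 for miR-532-3p and 2.52 for miR-200a#.

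With the U6 gap as a term in the limma model, none of the 350 assays passed, and 78 had an unadjusted p under 0.05. All 16 changed assays kept their sign, their log2 changes were a median of 0.85 of the values above, and their adjusted p ran from 0.0699 to 0.143. miR-130a stood at 1.49 ± 0.41 in that fit (adjusted p = 0.0699), at 1.35 ± 0.55 within the 14 samples without the gap (adjusted p = 0.267) and at 1.79 ± 0.50 within the 6 samples with it. Of the 16, 5 had a value more than 1.5 times smaller in 1 of these sets than over all samples. miR-200a# stood at 0.81 ± 0.51 and miR-10b at -1.10 ± 0.54 without the gap, and miR-1255B at 0.05 ± 0.60, miR-452 at 1.43 ± 0.69 and miR-28-3p at -1.27 ± 0.61 with it. No assay passed within either set, with 49 and 34 assays at an unadjusted p under 0.05 respectively. Other scalings changed both the number and the balance of calls: endogenous controls gave 0 higher and 2 lower, the sample median 3 and 3, quantile normalization 8 and 2, and unnormalized Ct 2 and 86. The median log2 change of all assays was -0.06 as reported, and -0.17, -0.11, 0.12 and -0.83 under these scalings. With animal as a fixed block 0 assays passed (27 at an unadjusted p under 0.05), and with animal as a random block all 16 passed. Single samples also moved the count: 2 assays passed without uninfected replicate 3 (HF54), 3 without replicate 4 or 8 (HR42 or IT05), 8 without replicate 5 (HT73), 6 without replicate 6 (IH95) and 27 without replicate 1 (HD08). Leaving out an infected sample gave 48 without replicate 2 (FT11), 34 without replicate 10 (HF54), 10 without replicate 8 (HD08), 6 without replicate 3 or 7 (HN15 or GA19) and 5 without replicate 4, 5 or 6 (HI68, HG45 or HB31).

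**Figure D2:**
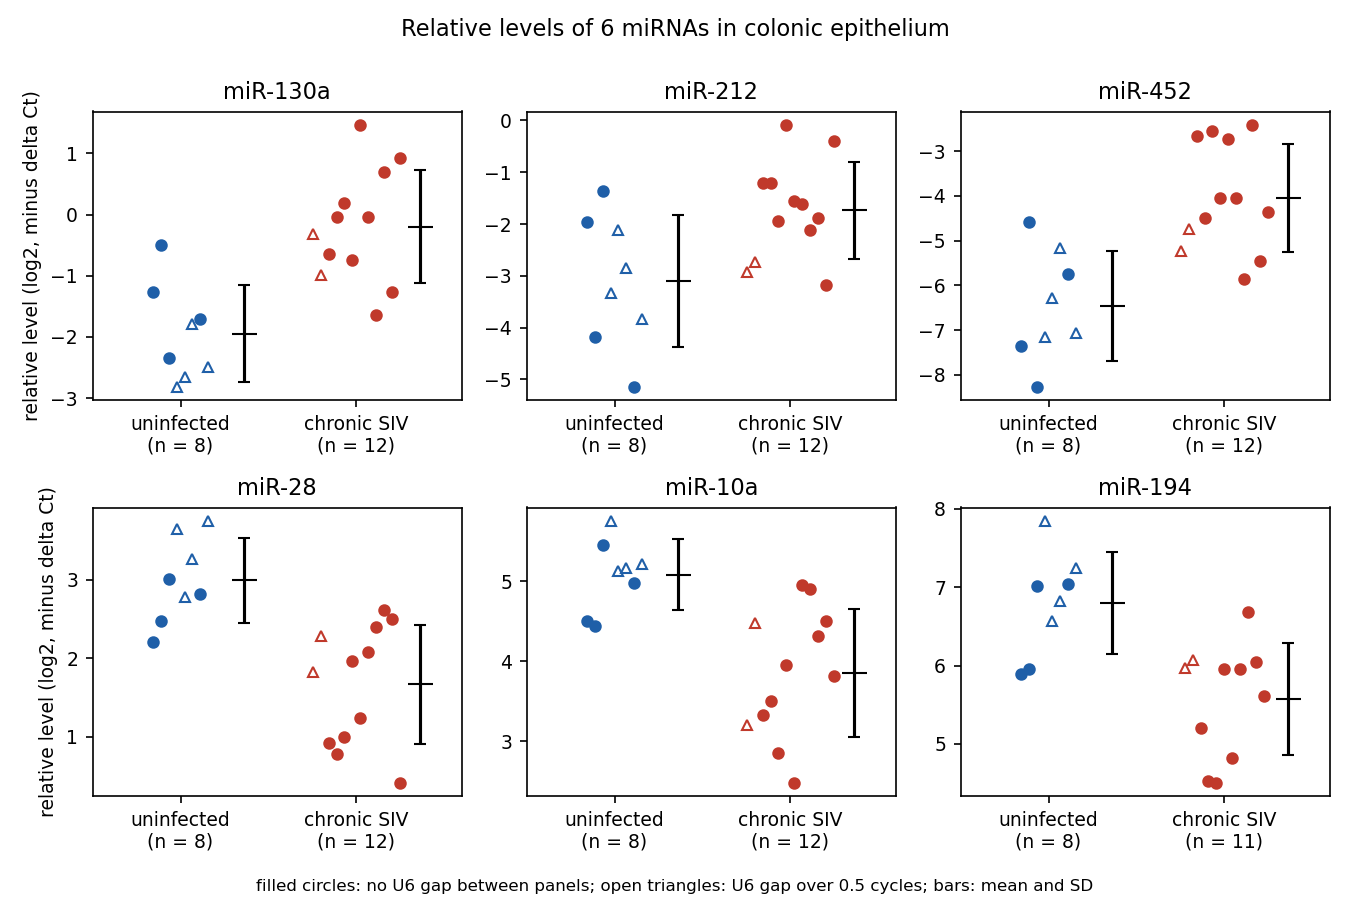
Relative levels (log2, y axes) of 6 miRNAs in each uninfected (blue) and chronic SIV (red) sample, with the mean and SD beside the points, and open triangles for the 6 samples with a U6 gap between panels. For miR-130a and miR-452 all 12 infected samples lie above the uninfected median, and for miR-28 and miR-10a all 12 lie below it.

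The 2 miRNAs recalled from the study's own publication, where they were linked to epithelial barrier disruption, were miR-130a, given above, and miR-212. miR-212 had a log2 change of 1.36 ± 0.49 SE (2.57-fold in size, adjusted p = 0.0765, higher in 11 of 12 infected samples) and did not pass over all assays. Adjusted over the list alone, both rose, but they were recalled from the publication on these same samples, so this is not independent evidence of their direction. Among 10 tested miRNAs reported to target tight junction components, 1 rose over all assays (miR-130a), 9 did not pass, and 3 rose when adjusted over the list alone: miR-130a, miR-874 (1.04 ± 0.36) and miR-212. This list holds the recalled pair, miR-130a and miR-212, so these 2 calls are not separate evidence from those above. The list as a whole did not pass (camera adjusted p = 0.158, and 0.478 with an estimated correlation), though it was higher under quantile normalization (camera adjusted p = 0.0044).

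Lists of cell type markers moved in opposite directions. Of 12 leukocyte-enriched miRNAs, 1 fell over all assays (miR-181a) and 11 did not pass, and 4 fell adjusted over the list alone: miR-181a, miR-181c (-1.37 ± 0.43), miR-342-3p (-1.54 ± 0.49) and miR-150 (-1.26 ± 0.42). The myeloid miR-223 was the 1 member with a positive value (1.10 ± 0.66). The list was lower as a whole, with a median log2 change of -0.96 (camera adjusted p = 0.0126), which did not hold with an estimated correlation (adjusted p = 0.478). Of 12 smooth muscle and fibroblast miRNAs, none passed singly, over all assays or adjusted over the list alone, and 11 had positive values, among them miR-143 (1.49 ± 0.58), miR-1 (2.18 ± 0.87) and miR-133b (1.72 ± 0.69). Within the 14 samples without the U6 gap, miR-143 stood at 1.09 ± 0.69, miR-1 at 1.23 ± 1.01 and miR-133b at 1.14 ± 0.82. The 12 tested members were higher as a whole, with a median of 0.94 (camera adjusted p = 0.0126), and the call was lost with an estimated correlation (adjusted p = 0.511). The thirteenth assay of this list, miR-199a-3p, amplified in too few samples to be tested for level and went the other way, with detection in 8 of 8 uninfected and 2 of 12 infected samples. Its mean Ct where detected was 22.1, far from the placeholder, and whether its non-detects reflect a lower level was not tested. The listed miR-199a and miR-199b had positive values (0.68 ± 0.59 and 0.79 ± 0.62). The imprinted DLK1-DIO3 cluster was also higher (median 0.52 over 20 members, camera adjusted p = 0.0199; adjusted p = 0.478 with an estimated correlation), with no member passing singly and values of 1.47 ± 0.56 for miR-494 and 0.91 ± 0.37 for miR-127. miR-494 stood at 0.67 ± 0.75 within the 14 samples without the U6 gap and at 2.35 ± 0.66 within the 6 with it. For miR-127 these values were 1.12 ± 0.47 and 0.07 ± 0.63. These 3 lists passed camera with the U6 gap as a term (each adjusted p = 0.0271, and 0.491 with an estimated correlation) and within the 14 samples without the gap (adjusted p = 0.0213 for smooth muscle and 0.0394 for the other 2). Under quantile normalization the smooth muscle list passed (adjusted p = 0.0044) and the leukocyte and DLK1-DIO3 lists did not (0.196 and 0.449).

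The remaining 8 tested lists did not pass as a whole (camera adjusted p of 0.158 to 0.932, and 0.606 to 0.961 with an estimated correlation). Of 8 miRNAs enriched in intestinal epithelium, 1 fell over all assays (miR-194) and 7 did not pass. Adjusted over the list alone, miR-194, miR-215 (-1.22 ± 0.41) and miR-196b (-1.26 ± 0.48) fell and miR-31 rose (2.31 ± 0.80), with miR-215 at -0.79 ± 0.35 with the U6 gap as a term and -0.75 ± 0.46 within the 14 samples without the gap. In the epithelial miR-200 family 0 of 5 passed over all assays, and miR-200c fell adjusted over the list alone (-0.97 ± 0.34, but -0.57 ± 0.26 with the U6 gap as a term and -0.31 ± 0.33 within the 14 samples without the gap), while the family's median was -0.18, its mean 0.26 and its camera direction down. In the let-7 and miR-98 family 0 of 8 passed over all assays, and miR-98 (-0.99 ± 0.32) and let-7f (-0.89 ± 0.29) fell adjusted over the list alone, against -0.55 ± 0.40 and -0.54 ± 0.36 within the 14 samples without the gap. This family was lower as a whole with the U6 gap as a term (camera adjusted p = 0.044; adjusted p = 0.491 with an estimated correlation). No member passed, over all assays or adjusted over the list alone, among 11 inflammation-responsive miRNAs (median -0.58, with miR-21 at -0.76 ± 0.35), 4 endothelial miRNAs (median -0.45, with miR-126 at 1.28 ± 0.61), 13 members of the miR-17-92 cluster and its paralogs (median -0.20, mean 0.08) or the 3 of the miR-29 family (median 0.16, mean -0.07). Within the 14 samples without the gap miR-21 stood at -0.21 ± 0.33 and miR-126 at 0.37 ± 0.74. In the miR-130 and miR-301 family miR-130a was the 1 of 5 that rose, over all assays and adjusted over the list alone (median -0.03, mean 0.30). In the erythroid, miR-34 and miR-449, and hypoxia lists, with fewer than 3 tested members each, none passed over all assays. Adjusted over the list alone, miR-34a fell (-1.68 ± 0.71, the 1 tested member of its list), but it stood at -0.77 ± 0.52 with the U6 gap as a term and at -0.08 ± 0.53 within the 14 samples without the gap. Its level differed by 2.72 between samples with and without the gap (adjusted p = 0.00151). Also adjusted over the list alone, the 2 erythroid members (median 0.95) and the hypoxia-responsive miR-210 (0.59) did not pass.

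**Figure D3:**
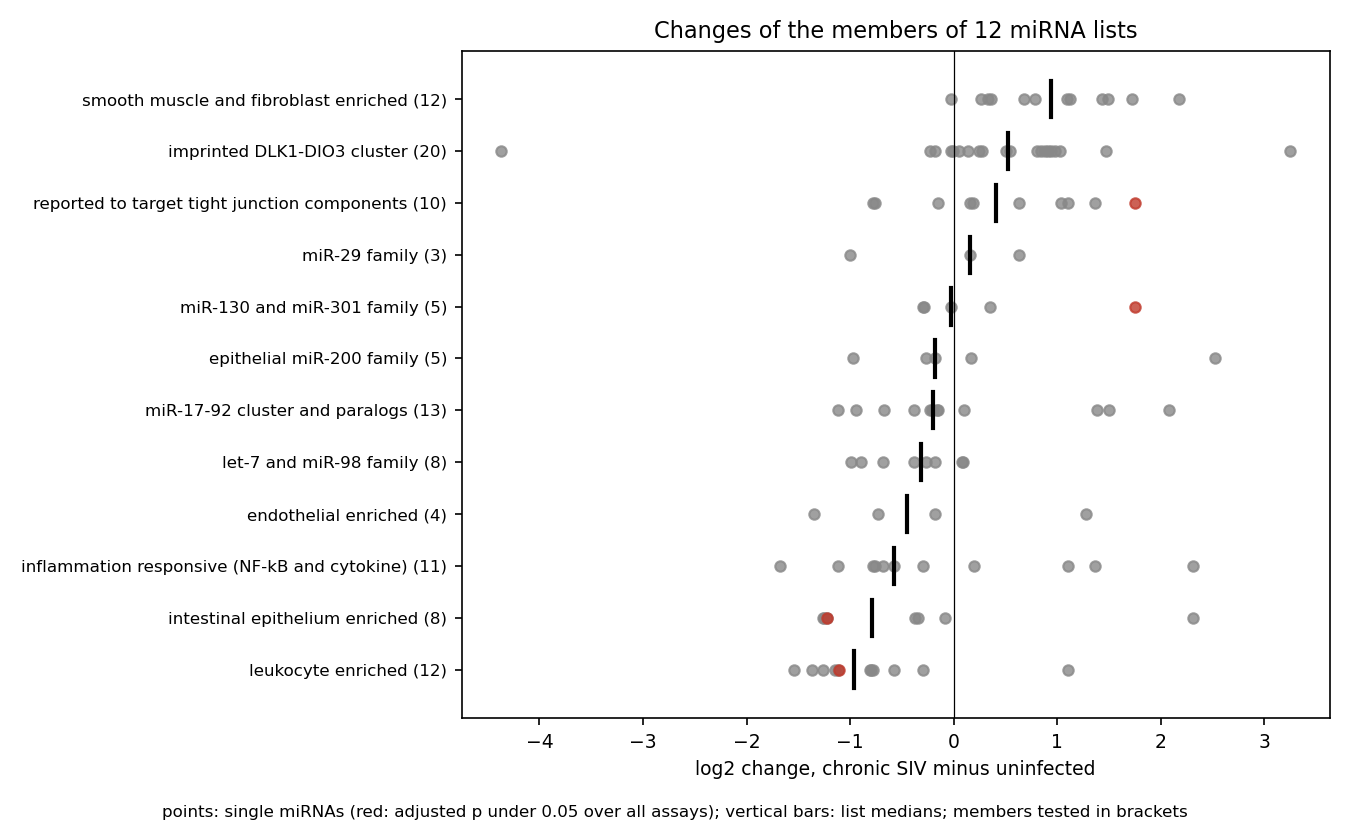
Log2 change between chronic SIV and uninfected samples (x axis) for each tested member of the 12 lists with at least 3 members, with red points for members past an adjusted p of 0.05 over all assays and vertical bars at list medians. The leukocyte list has a median of -0.96 and the smooth muscle list a median of 0.94.

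In the 4 serially sampled animals, no assay changed from before to after infection at an adjusted p under 0.05 (limma with animal as a block, 27 assays at an unadjusted p under 0.05). The smallest adjusted p was 0.0648, for 1 of 2 assays for miR-378 (assay 002243, log2 change -9.03 ± 0.89 SE, measured in 3 pairs) and for miR-520e (-7.13 ± 0.91, lower in 4 of 4 animals). Both had early mean Cts over the uninfected samples, 11.68 ± 3.76 (SD, n = 7) and 12.67 ± 1.49 (SD, n = 8). Before infection 11, 18, 14 and 10 miRNA assays had Cts below 12 in HD08, HH07, HF54 and HR42. After infection 4, 4, 2 and 3 did. Whether such early Cts measure abundance was not tested. Among positive values, the smallest p belonged to miR-193a-3p (4.59 ± 0.60, higher in the 3 animals measured), miR-99b (6.98 ± 1.14, 3 of 3) and miR-193b# (5.34 ± 0.89, higher in the 2 animals measured). miR-31 was higher in 4 of 4 animals (2.58 ± 0.66). miR-130a was higher after infection in 3 of 4 animals (1.17 ± 0.78, adjusted p = 0.711), with changes of 1.24 in HD08, -1.16 in HH07, 3.05 in HF54 and 1.55 in HR42. In the HF54 sample after infection the reference mean Ct was 21.08 on panel A and 25.66 on panel B, against 20.32 and 22.12 before. It had 112 panel B assays detected, against 165 before. The late panel B raised its joint reference, so HF54 changes of panel A assays such as miR-130a and miR-31 sit higher. miR-194 (-0.60 ± 0.65) and miR-10a (-0.37 ± 0.56) were each lower after infection in 2 of 4 animals, HF54 and HR42, and higher in HD08 and HH07. On simulated data this comparison found 3.01% of changes of 3 log2 units, so it could show only very large changes. In HR42 only the sample before infection had the U6 gap, and without that animal 0 assays passed (36 at an unadjusted p under 0.05). Without HF54 or HH07, 1 assay passed.

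Among animals sampled once, 11 of 350 assays differed between 8 infected and 4 uninfected animals (limma, 3 higher and 8 lower in infected, 100 at an unadjusted p under 0.05). These 4 uninfected animals may be those given only THC or vehicle, so THC cannot be told apart from infection here. miR-130a rose by 2.14 ± 0.48 on the log2 scale, miR-200a# by 2.30 ± 0.55 and miR-494, a member of the imprinted DLK1-DIO3 cluster, by 2.10 ± 0.51. The 8 lower assays were miR-338-5P, miR-28-3p, miR-28, miR-10a, miR-181a, miR-107 (-1.80 ± 0.37), the epithelial miR-200c (-1.47 ± 0.36) and the p53-responsive miR-34a (-2.97 ± 0.72). Apart from miR-338-5P (adjusted p = 0.000377), each had an adjusted p of 0.0474. The miR-338-5P value rests on the 2 uninfected animals of 4 that amplified it, EJ34 and IT05, at Cts of 6.225 and 6.027. With Cts below 12 treated as not measured, miR-338-5P was no longer tested. No assay passed in that fit, miR-130a included (limma, 100 at an unadjusted p under 0.05). Among the calls, 7 of the 11 were among the 16 called over all samples, which include these 12. With the U6 gap as a term 1 assay passed, miR-338-5P, and miR-130a stood at 1.76 (adjusted p = 0.156). Without uninfected replicate 5, 6, 7 or 8 (HT73, IH95, EJ34 or IT05) 5, 2, 38 and 1 assays passed. Without infected replicate 1 or 2 (FE24 or FT11) 28 and 64 did, and without any of replicates 3 to 7 (HN15, HI68, HG45, HB31 or GA19) 1 did. Other scalings gave 0 higher and 1 lower with endogenous controls or quantile normalization, 1 and 16 with the sample median, and 0 and 72 with unnormalized Ct.

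The comparison within serial animals and the one among animals sampled once share no animal. Across the 350 assays, which are not independent replicates, their log2 changes had a Pearson r of 0.53 and a Spearman rho of 0.44, and 66.6% had the same sign. When HR42 was left out of the first and the U6 gap was a term in the second, r was 0.13 and rho 0.03 over 342 assays, and 50% had the same sign.

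No assay passed a test of whether the effect of infection differed between serially sampled animals and animals sampled once (limma interaction term, 0 of 350 at an adjusted p under 0.05, 26 at an unadjusted p under 0.05). This does not show equal effects, since the interaction was measured with a larger error, as for miR-130a (-0.97 ± 0.84, against an error of 0.41 for infection over all samples). The smallest p values belonged to miR-193a-3p (5.49 ± 1.57 SE, adjusted p = 0.555), miR-1293 (-3.55 ± 1.07) and miR-10b# (-2.24 ± 0.70). miR-28 and miR-107 had interaction values of 1.41 ± 0.58 and 1.64 ± 0.58 (both adjusted p = 0.576). With the U6 gap as a term 0 assays passed (30 at an unadjusted p under 0.05), and without uninfected replicate 5, 7 or 8 (HT73, EJ34 or IT05) 1 did.

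Between uninfected samples taken before infection and those of animals sampled once, no assay passed (limma, 0 of 350, 30 at an unadjusted p under 0.05), with the smallest p for miR-662 (-3.90 ± 0.98 SE, adjusted p = 0.391), miR-601 (9.08 ± 2.18) and miR-95 (1.47 ± 0.39). Of these 4 and 4 samples, 1 and 3 had the U6 gap, and 0 assays passed with the gap as a term (27 at an unadjusted p under 0.05). The 4 animals sampled once may be those given only THC or vehicle. Without uninfected replicate 7 (EJ34) 2 assays passed. Between infected samples of serial animals and of animals sampled once, 1 assay of 350 differed. miR-302b, of a cluster known from embryonic stem cells, was lower in the serial animals (-6.75 ± 1.03, adjusted p = 0.0201, 50 assays at an unadjusted p under 0.05), and it passed with the U6 gap as a term. The gut epithelial miR-192 had a value of 1.26 ± 0.33 and did not pass (adjusted p = 0.194). The miR-302b call was lost without infected replicate 6, 8, 9 or 10 (HB31, HD08, HH07 or HF54), leaving 0 assays in each case, and 2 assays passed without replicate 11 or 12 (HR42 or HV48). The sample median gave 12 higher and 1 lower.

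Among 197 assays that amplified in 3 to 17 of the 20 samples, none passed a test for a difference in detection between the groups (two-sided Fisher's exact test, 0 at an adjusted p under 0.05). At an unadjusted p under 0.05 there were 10, all detected more often in uninfected samples. miR-199a-3p, known from mesenchymal cells, amplified in 8 of 8 uninfected and 2 of 12 infected samples (exact p = 0.000714, adjusted p = 0.0758), and miR-449, known from ciliated epithelium, in 7 of 8 and 1 of 12 (exact p = 0.00077, adjusted p = 0.0758). Where detected, their mean Cts were 22.1 and 32.3. Whether the loss of miR-199a-3p, at so early a Ct, reflects its level was not tested. miR-345 and miR-491-3p each amplified in 4 of 8 and 0 of 12 (adjusted p = 0.481), and miR-184 in 8 of 8 and 5 of 12 (adjusted p = 0.481). Within the 14 samples without the U6 gap, miR-199a-3p amplified in 4 of 4 uninfected and 0 of 10 infected samples, and miR-449 in 3 of 4 and 1 of 10. Within the 6 with the gap, miR-199a-3p amplified in 4 of 4 and 2 of 2, showing no difference there, and miR-449 in 4 of 4 and 0 of 2.

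The authors' deposited table of fold changes gave values for 754 assays, of which 282 had an adjusted p under 0.05, 249 higher and 33 lower. In the authors' deposited table miR-130a was 3.57-fold higher (adjusted p = 0.0165) and miR-212 2.73-fold higher (adjusted p = 0.0347), both in the direction of the values above. The column is headed as a ratio to preinfection samples, but with a Ct of 40 counted as measured its log2 values followed a comparison with all 8 uninfected samples with a Pearson r that rounded to 1 over 754 assays, against 0.79 for the 4 taken before infection. Of the 16 assays called here, 14 were also called in the authors' deposited table and all 16 had the same direction. Across 350 assays the log2 of the deposited fold changes and those computed here had a Pearson r of 0.68 and a Spearman rho of 0.73, with the same sign in 85.1%. The authors' deposited table also called each of the 167 assays that amplified in no sample, which shared 1 fold change of 1.81 and 1 adjusted p of 0.0165 and made up 59.2% of its calls. A further 58 calls were on assays detected in 1 to 14 samples, and 57 on assays detected in at least 15.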

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

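The tests of the never amplified assays, of miR-143 against miR-145 and of splits that part the serial pairs were chosen after the result was seen. Among 34 groups of samples searched for a single distant value, 1 stood out, where chance gives about 1 in 20. The miR-338-5P level in uninfected replicate 3 (HF54) was -3.98, against 13.43 to 14.97 in the other 4 uninfected samples that amplified it (n = 5, gap over range 0.919). The 10 infected samples lay between -7.65 and 2.77, so this sample sat with them. The Cts of the other 4 uninfected samples were earlier than the mean U6 Ct, so it is not settled that HF54 is the unusual one. No explanation of the HF54 value or of those 4 values was tested.

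The first pattern weighed is the set of 16 assays called between infected and uninfected samples. Of 100 splits of the 20 samples, 1 gave as many calls, the real one, with 2 in the highest other. Of 100 splits that part all 4 serial pairs, as the real one does, again 1 did, with 1 in the highest other. No other drawn split thus came near this count, but the splits were not matched for the U6 gap. The fixed animal block and the U6 gap as a term each gave 0 calls. With each sample's mean Ct as a covariate, the log2 changes were a median of 0.8 ± 0.05 (SE over assays, n = 16) of those without it. This value goes against lower template as the whole cause but cannot decide it. The 16 assays share the same 20 samples and were chosen as calls, so the SE does not measure the spread between samples. The mean Ct covariate also ended every call (limma, 0 passing, 71 at an unadjusted p under 0.05): miR-130a went from 1.75 ± 0.41 to 1.35 ± 0.50 (adjusted p = 0.212), a smaller change with a larger error. The panel gap remains a candidate explanation for the 11 calls in animals sampled once, since their median signed change in the 3 serial pairs without a gap was 0.2 ± 0.76 (SE), with 0.4 in HD08, -0.03 in HH07 and 0.47 in HF54, and infection, THC and animal differences stay open.

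Other splits of the samples bear on the remaining counts. Among animals sampled once, 2 of 100 splits gave as many as the real 11 calls, and the highest other, 14, put 4 of the 5 gap samples in its group of 4. The other 2 drawn splits that did so gave 2 and 5, so a split along this possible batch can give as many calls but did not always. With the gap as a term 1 assay passed there. Chance could not be excluded between the 2 kinds of infected sample (9 of 100 splits gave the real 1 or more, highest other 1). With a real count of 0 every split gives at least as many, so the 35 of 35 splits between the 2 kinds of uninfected sample and the 100 of 100 for the interaction (highest other 34) decide nothing about chance. The highest of the 35, with 69 calls, was exactly the split by U6 gap, which points to that structure of the samples. The serial animals allow 8 splits, all 8 with 0 calls, too few for a share under 0.05.

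The second pattern is the higher smooth muscle list and lower leukocyte list. More muscle or stroma in the infected isolates stays open as the cause, and the values go both ways. Of the 12 tested members 11 had positive values and none passed, from 2.18 for miR-1 to -0.03 for miR-125b. miR-143 moved by 1.16 ± 0.39 (SE, n = 20) more on the log2 scale than miR-145 from the same transcript, a pair picked for that difference that excludes nothing. miR-199a-3p was detected in 8 of 8 uninfected and 2 of 12 infected samples. Its mean Ct where detected was 22.1, and whether its non-detects reflect a lower level was not tested. Within the 14 samples without a gap the difference between the list medians was 1.6 (exact permutation p = 0.048). This goes against the panel gap as the whole cause but does not decide it. The lists were picked on all 20 samples, these 14 among them, and the permutation ignored the pairing of HD08, HH07 and HF54. Regulation by infection stays open too, and neither list passed with an estimated correlation.

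The third pattern is that the deposited table called all 167 assays that never amplified. A reference that differs between groups, subtracted from a fixed Ct of 40, would give them 1 shared fold change, and they had 1, of 1.81 or 0.86 on the log2 scale. The reference used here differed by 0.77 cycles. With 40 counted as measured, the deposited log2 values followed a comparison with all 8 uninfected samples with a Pearson r that rounded to 1 over 754 assays. Both results point to the placeholder being treated as a measured Ct. The 167 assays had no measured level in any sample, so their calls say nothing about miRNA levels.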

How the results depend on the processing

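The alternatives with the U6 gap, a reference per panel, Cts below 12 treated as not measured and pairs without a gap were chosen after seeing the data. Except where construction is named, the cause of each difference below was not tested. The 16 calls between infected and uninfected samples became 2 with endogenous controls, 6 with the sample median, 10 with quantile normalization, 88 with no normalization, 10 with assays detected in at least 10 of 20 samples, 7 with non-detects set to 40 and 8 with a rank-sum test. Animal as a fixed block, which uses changes within 4 animals, the U6 gap as a term, and the 14 samples without or the 6 with a gap each gave 0 (limma, 27, 78, 49 and 34 at an unadjusted p under 0.05). Leaving out 1 sample gave 2 to 48. Counts of 12 to 16 came from a limit of Ct 37, assays detected in all 20 samples, trend and robust settings, animal as a random block, a reference per panel and Cts below 12 not measured.

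In the serial animals the 0 calls became 2 with endogenous controls, 1 with assays detected in all 20 or in at least 10 samples, and 3 unpaired, and leaving out 1 animal gave 0 to 1. Among animals sampled once the 11 calls became 1 with endogenous controls, 17 with the sample median, 1 with quantile normalization, 72 with no normalization, 45 with assays detected in all 20 samples, 1 with at least 10, 0 with non-detects set to 40 (92 at an unadjusted p under 0.05), 33 with trend and robust settings, 1 with a reference per panel, 0 with Cts below 12 not measured (100 at an unadjusted p under 0.05) and 1 with the gap as a term. Leaving out 1 sample there gave 1 to 64. Between the 2 kinds of infected sample the 1 call became 13 with the sample median and 0 with quantile normalization, assays detected in all 20 samples or non-detects set to 40 (55, 35 and 37 at an unadjusted p under 0.05), and 0 to 2 when 1 sample was left out. The interaction gave 0 to 1 and the 2 kinds of uninfected sample 0 to 2 when 1 sample was left out, and both gave 0 under every other alternative run. Detection gave 0 under its 3 alternatives.

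The 3 lists called became 0 with an estimated correlation, and 2 to 4 under the other alternatives. The tight junction list passed with quantile normalization, where the leukocyte and DLK1-DIO3 lists did not, and the let-7 list with the gap as a term. DLK1-DIO3 did not pass with assays detected in all 20 samples (0.0836). Lists that changed direction, with their adjusted p, were not called either way. With quantile normalization these were miR-200 (0.0758), intestinal epithelium (0.677), endothelial (0.677), inflammation (0.449), let-7 (0.677) and miR-17-92 (0.0821). With assays detected in all 20 samples they were endothelial and miR-17-92 (both 0.982). With the gap as a term they were endothelial (0.9), inflammation (0.883), miR-17-92 (0.412) and miR-29 (0.9), and in the 14 samples without a gap the same 4 at 0.871, 0.523, 0.383 and 0.871.

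Among the 16 called assays, 1 changed sign under 1 alternative, miR-30b with quantile normalization (0.14). Other named miRNAs that changed sign between infected and uninfected samples, with their log2 change, did not pass as reported or under that alternative. With quantile normalization these were miR-200c (0.8), miR-429 (0.63), miR-215 (0.11), miR-222 (0.62), miR-21 (0.19), let-7e (0.3) and let-7d (0.19). With no normalization they were miR-200b (-0.6), miR-451 (-0.17), miR-29b (-0.14), miR-29a (-0.61), miR-454 (-0.42) and miR-210 (-0.18). With animal as a fixed block they were miR-429 (0.21), miR-196b (0.06), miR-222 (0.35), let-7e (0.08) and miR-301b (0.47), and with non-detects set to 40 miR-874 (-0.18). With the gap as a term they were miR-222 (0.29) and miR-301b (0.01). In the 14 samples without a gap they were miR-429 (0.03), miR-222 (0.38), miR-454 (-0.48) and miR-301b (0.36), and in the 6 with one miR-200b (-0.19), miR-486 (-0.29), miR-451 (-0.44), miR-424 (0.34), miR-222 (0.12) and miR-29b (-0.1). In other comparisons, non-detects set to 40 reversed miR-193b# after infection (-3.06), miR-1293 (1.16) and miR-92a-1# (2.85) in the interaction, and miR-1208 (-1.61), miR-296 (-1.37) and miR-331-5p (8.79) between the 2 kinds of uninfected sample. For named miRNAs over all samples, the alternatives fixed before the data were seen left 582 values with the same direction and side of the threshold, 79 no longer past it and 17 newly past it.

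The correlation with the deposited fold changes was 0.65 to 0.68 under all scalings run. The number of samples limits precision: changes of 1 log2 unit were found in 25.3% of simulated cases over all samples.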

Other observations

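The tests in this part were written before their results were seen, and the miR-23 and miR-27 members were picked after theirs. If infection acted on transcription of the precursors, both arms of a precursor might change together. Across 72 precursors with both arms tested, which are not independent replicates, the log2 changes of the arms had a Spearman rho of 0.11 (one-sided permutation p = 0.178) and a Pearson r of -0.08, with 39 of the same sign. miRNA genes within 10 kb of each other might also change together. Over 39 neighbouring pairs among 62 genes the mean absolute difference in log2 change was 1.15, against 1.33 in random pairings (one-sided permutation p = 0.0703), and 24 pairs had the same sign. Neither hypothesis was borne out at the threshold.

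Closely related miRNAs had values of opposite sign between infected and uninfected samples, none passing over all assays. miR-27b and miR-23b stood at -1.13 ± 0.37 and -1.14 ± 0.38 SE, and miR-27a and miR-23a at 2.18 ± 0.85 and 1.34 ± 0.94. Within the 14 samples without the U6 gap the values were -0.18 ± 0.31 for miR-27b, -0.56 ± 0.48 for miR-23b, 0.25 ± 0.61 for miR-27a and 0.01 ± 0.34 for miR-23a.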
